A study of Mus musculus with 6 samples.

How the data were processed

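Gene expression was measured by RNA-seq in 6 libraries from 2 sorted populations, Nanog+E-cadherin+ and Nanog+E-cadherin- cells, with 3 replicates each. Per the labels' protocols, neural stem cells of postnatal day 4 mice were reprogrammed by doxycycline until day 7, fixed, permeabilised, stained for E-cadherin and Nanog, sorted and reversed from crosslinking before RNA isolation, and libraries were made with a TruSeq RNA kit. Groups and replicate numbers come from the sample titles. Per the submitters' processing notes, the tools named are Bowtie and RSEM 1.2.4 and the genome build is mm9. Their settings and whether strand was used in counting are not given in the sources used here, so a gene and its antisense partner cannot be told apart. RSEM divides reads that match several genes, so genes with near-identical copies or repeat sequence are uncertain.

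Per the file headers, each deposited file gives for each gene an expected count, a TPM value and an FPKM value, together with a transcript length and an effective length that held the same values. The expected counts deposited by the authors need not be whole, and they were rounded to whole numbers before any count test. The authors' TPM values were used only for alternatives, as log2(TPM + 1) and log2(TPM + 0.1), and the authors' FPKM values were not used. Genome coordinates are not printed, because the reference at hand is of another build. Some genes of the lists were not found in the files and were not analysed here.

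Total expected counts per library ran from 8851110 to 39630916, so a gene at 5 CPM had about 44.3 counts in the shallowest library. The main test was edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total 15), quasi-likelihood fits and Benjamini-Hochberg adjustment, on all 6 libraries with group as the only term. CPM values are scaled by TMM, except that sums over background genes and values of genes below the filter are CPM of library totals. All log2 fold changes are Nanog+E-cadherin+ over Nanog+E-cadherin-. The threshold was an adjusted p under 0.05. The 28 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 over lists with at least 3 tested genes, beside camera with an estimated correlation and fry. Of these, 27 were tested and 6 passed with the preset correlation. With an estimated correlation 0 passed (smallest adjusted p = 0.147), and with fry 0 passed (smallest 0.229). With the replicate block 11 lists passed with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.246) and 0 with fry (smallest 0.0993). Cdh1 and Nanog were also tested by exact two-sided permutation of log2 CPM.

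The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the gate and cassette genes Nanog, Cdh1, Pou5f1, Sox2, Klf4 and Myc. It adds the 12 genes of largest rise and the 12 of largest fall with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between libraries, passing over predicted and clone-named genes and pseudogenes. Where none pass, it takes the 5 of smallest p in each direction. Last, it takes each list's measured key genes and up to 4 further members of smallest p. Applying the second part to the fit with the replicate block, which gave 12 higher and 3 lower genes, was decided after the data were seen, as was naming further genes said to have passed over a list alone.

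Both groups carry replicate numbers 1 to 3, so pairing was checked from the correlation across genes of deviations from the group means. Same-numbered libraries correlated at 0.75, 0.41 and 0.48, all above the limit of 0.1, and differently numbered ones between -0.62 and 0.12. The pairing thus comes from the values, since the labels do not say that a number marks a shared culture. Y-linked genes were near 0 in both libraries numbered 2 alone, so the spread between replicates is not only technical. The fit with the replicate block had a biological coefficient of variation of 0.285, against 0.499 without it, and its values are given where they change a call.

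The steps were tested on simulated data of these samples' means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. In data simulated with pairs, the comparison of both populations with the replicate block recovered 42 of 100 genes changed 2-fold and 81 of 100 changed 4-fold, with 4 wrong calls among 13260 unchanged genes. With group only it recovered 0 of 100 at either size. In data simulated without pairs, group only recovered 31 of 100 changed 4-fold with 5 wrong calls, and the replicate block 0 of 100. DESeq2 with the block made 23 wrong calls with pairs and 87 without (edgeR 4 and 0), and with group only 0 and 44 (edgeR 0 and 5). The edgeR block with 2 of the pairs made 25, and limma-voom with group only made 0 in either case. Limma-voom with the block was not simulated. Over 5 simulated lists with raised genes, camera found 5 with the preset and 0 with an estimated correlation, and fry found 5, with 0 of 20 unchanged lists called by any of these. The simulated genes were drawn independently, so wrong list calls that come from correlation between genes could not arise there. In the real data the estimated correlation was 0.63 for the G2-M list, so these counts do not rank the list tests for such lists.

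Alternatives were DESeq2 1.42.0 size factors, upper quartile factors, library totals, no filter, at least 5 CPM on average, DESeq2's Wald test, limma-voom, robust quasi-likelihood, limma on log2 TPM, the replicate block, glmTreat against a 1.5-fold change, and leaving out each library. LINE-1 sequence was searched as 24-base words in mouse GENCODE M21 transcripts, where 20221 of 20325 genes (99.5%) had a sequence, 20007 of them matched by RefSeq accession. A gene with at least 10 such words was taken to hold LINE-1 sequence. The search was added after the data were seen. Its words were widened from a starting set in 5 rounds, and stopping there was decided after seeing that the next round grew steeply. GC and length offsets covered 99.8% of the genes tested.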

Results

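RNA was sequenced from mouse neural stem cells, the self-renewing precursors of neurons and glia, that were being reprogrammed toward pluripotency. The cells came from mice at postnatal day 4 that carried a doxycycline-inducible cassette of Oct4 (Pou5f1), Sox2, Klf4 and Myc, and were collected at day 7 of induction. After fixation they were stained and sorted for the pluripotency factor Nanog and for the epithelial adhesion protein E-cadherin (Cdh1). Nanog+E-cadherin+ cells (n = 3) were compared with Nanog+E-cadherin- cells (n = 3), which asks how the transcriptomes of Nanog-expressing cells with and without E-cadherin differ. Each file listed 20325 genes. Total expected counts were 20934553, 12345327 and 19241426 in Nanog+E-cadherin+ replicates 1 to 3, and 39630916, 10825811 and 8851110 in Nanog+E-cadherin- replicates 1 to 3. Genes with a value above 0 numbered between 13833 and 16407 per library, lowest in Nanog+E-cadherin- replicate 3. At totals matched to the shallowest library, that library had 13826 such genes and the others 14905 to 16041, so depth alone does not account for it. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples.

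Cdh1 mRNA followed the sort, and Nanog mRNA did not differ beyond the spread between libraries. Cdh1 stood at 129 ± 21.4 CPM (SD, n = 3) in Nanog+E-cadherin+ cells and at 17.4 ± 2.53 CPM (SD, n = 3) in Nanog+E-cadherin- cells, a 7.39-fold difference with no overlap between libraries. Nanog stood at 116.6 ± 15.1 CPM against 107 ± 28.3 CPM (SD, n = 3 each), a log2 fold change of 0.12 ± 0.25 (SE). The reprogramming factors had log2 fold changes of 0.38 ± 0.31 for Pou5f1, -0.16 ± 0.25 for Sox2, -0.25 ± 0.29 for Klf4 and -0.01 ± 0.25 for Myc (SE), and none of the 4 passed the test. Their counts can hold transcripts of the inducible cassette as well as of the endogenous genes. For Cdh1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 fold change of 2.89 ± 0.24 (SE) and an adjusted p of 0.0608 with group as the only term. With the replicate number as a block the log2 fold change was 2.87 ± 0.19 (SE) and the adjusted p was 0.00177. The exact two-sided permutation test gave p = 0.1 for Cdh1, the smallest value that 3 libraries against 3 allow, and p = 0.7 for Nanog.

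**Figure D1:**
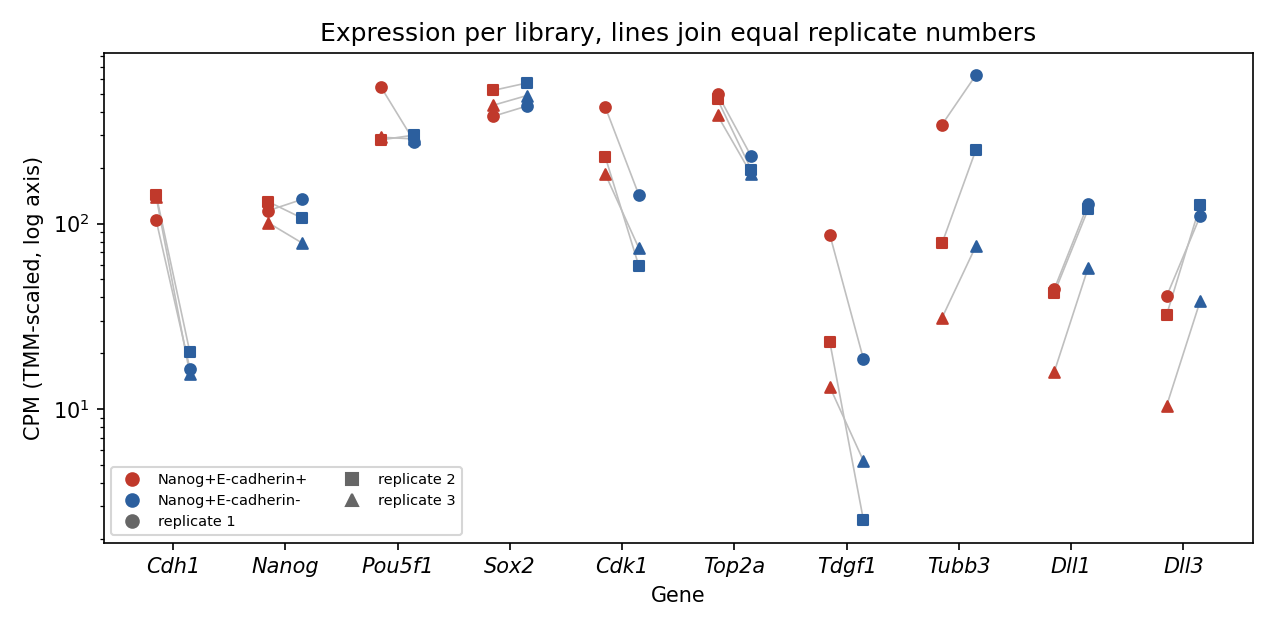
Each point is the CPM (log axis) of 1 gene in 1 library, red for Nanog+E-cadherin+ and blue for Nanog+E-cadherin-, with the marker shape giving the replicate number and grey lines joining equal numbers (n = 3 per group). Cdh1, Cdk1, Top2a and Tdgf1 lie higher, and Tubb3, Dll1 and Dll3 lower, in the Nanog+E-cadherin+ library of all 3 pairs, while Nanog is higher in 2 pairs and lower in 1.

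Genes of mitosis were prominent among those higher in Nanog+E-cadherin+ cells. With the replicate number as a block, 29 genes rose and 12 fell, and 10 of the 29 belong to a list of 24 G2-M genes. Among those that rose were Cdk1, the kinase that drives entry into mitosis (280 ± 128 against 91.6 ± 44.6 CPM, SD, n = 3 each), and Top2a, the topoisomerase that untangles replicated DNA (451 ± 60.5 against 204 ± 23.8 CPM). Cdk1 was 3.08-fold and Top2a 2.20-fold higher in the blocked fit. The mitotic kinases Plk1, Aurka and Aurkb, the spindle proteins Kif18b, Prc1, Nusap1, Spc25 and Troap, the spindle-associated Fam83d, the ubiquitin-conjugating enzyme Ube2c, cyclin F (Ccnf) and the importin Kpna2 also rose, although Spc25 did not pass with scaling by library totals or with a robust fit. All 24 G2-M genes had a fitted change above 0 (23 when scaled by library totals alone), and the median log2 fold change was 1.02. Adjusted over all genes, 0 of the 24 passed in edgeR's test with group only and 10 with the block. Adjusted over the list alone, 17 passed with group only and 20 with the block. The list passed camera (adjusted p = 5.49e-37), and it did not with an estimated correlation (adjusted p = 0.147) or with fry (adjusted p = 0.229). The count of 17 was 0 without Nanog+E-cadherin+ replicate 1, 0 without Nanog+E-cadherin- replicate 2 and 5 without Nanog+E-cadherin- replicate 3. It was 10 without Nanog+E-cadherin+ replicate 2, 16 without Nanog+E-cadherin+ replicate 3 and 18 without Nanog+E-cadherin- replicate 1. Leaving out 1 library unbalances the replicate numbers between groups. The blocked count of 20 was 19, 20 and 23 without both libraries numbered 1, 2 and 3. Those fits hold 2 pairs, which made more wrong calls in simulated data than 3 did. Without both libraries with background sequence the group-only median was 0.75, with Nanog+E-cadherin- replicate 1 alone in its group. The list also passed camera in 6 of the 9 other splits of the 6 libraries into 3 against 3 (adjusted p from 6.05e-14 to 0.0104). Each other split still sets 2 libraries of 1 group against 2 of the other, so a group difference can carry over into it. The G1-S and DNA replication genes had a smaller median log2 fold change of 0.45, and 23 of 24 were fitted higher. Among them, Pcna had a log2 fold change of 0.74 ± 0.14 and Ccne1 one of 0.76 ± 0.18 (SE, blocked fit). None passed over all genes in either fit. Adjusted over the list alone, 0 passed with group only, while with the block 15 rose and Tyms, which holds LINE-1 sequence, fell. Without both libraries numbered 1, 16 rose and 1 fell. Without those numbered 2, 4 rose and 0 fell, and without those numbered 3, 18 rose and 1 fell. With group only the median was 0.29 without Nanog+E-cadherin+ replicate 1, 0.27 without Nanog+E-cadherin- replicate 3 and 0.87 without Nanog+E-cadherin- replicate 1, where 12 genes passed higher and 1 lower over the list alone. Without both libraries with background sequence it was -0.07. This list also passed camera (adjusted p = 2.29e-07), with an adjusted p = 0.599 with an estimated correlation and 0.725 with fry.

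Over all 13460 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with group as the only term, where 359 had an unadjusted p under 0.05 and 673 would by chance. The same test with the replicate block called 41, with 1440 under an unadjusted p of 0.05 (742 higher, 698 lower). DESeq2's Wald test with group only called 21, with 490 under that p, and limma-voom with group only called 0, with 256. DESeq2 gave no adjusted p for 7834 genes, and 16 of its 21 calls were among the 41. Its other 5 calls, named after their values were seen, were Foxm1 and Kif23, which were higher, and Olfr613, Synj2bp and Zfp277, which were lower and were among the genes raised in 2 libraries with background sequence. In the 6 libraries, 504 genes were higher and 437 lower in every Nanog+E-cadherin+ library than in every Nanog+E-cadherin- library, together 6.99% of the genes tested. Chance gives 10% for 3 against 3 if all libraries are interchangeable, which the pairing by replicate number goes against. The 5 genes of smallest p in each direction with group only, which did not pass, were Cdh1, Kif18b, Kpna2, Prc1 and Ccnf (higher) and Spnb3, Chrnb2, Nsg2, Scrt1 and Kif5c (lower).

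Several neuronal genes were lower in Nanog+E-cadherin+ cells, and in edgeR's test with all 6 libraries they passed only with the replicate block. Tubb3, the neuronal beta-tubulin, stood at 151 ± 168 CPM against 319 ± 285 CPM (SD, n = 3 each) and fell in the blocked fit, by 1.27 ± 0.17 on the log2 scale (SE, adjusted p = 0.0370 in edgeR's test). The Notch ligands Dll1 and Dll3, the cadherin-family receptor Celsr3 and the neuronal endosomal protein Nsg2 also fell, with log2 fold changes of -1.62 ± 0.17, -1.76 ± 0.19, -1.60 ± 0.22 and -1.41 ± 0.20 (SE). Of 16 neuron genes tested, 13 were fitted lower, with a median log2 fold change of -1.12 with group only and -0.69 with the block. With group only the median was -0.50 without Nanog+E-cadherin- replicate 1, where 2 genes passed over the list alone, and -0.57 without Nanog+E-cadherin+ replicate 3. Adjusted over all genes, 0 passed with group only and 1, Tubb3, with the block. Adjusted over the list alone, 0 passed with group only and 7 with the block, namely Tubb3, Mapt, Ncam1, Syp, Dlx1, Dcx and Gad2. Stmn2 (211.9 against 190.6 CPM) and Gap43 (14.6 against 13.3 CPM) did not pass in either fit. The list passed camera (adjusted p = 1.04e-06), and it did not with an estimated correlation (adjusted p = 0.311) or with fry (adjusted p = 0.560). Without Nanog+E-cadherin- replicate 1 camera gave 0.0727, and without both libraries numbered 1 the blocked count over the list alone was 2, while without those numbered 2 it was 4 lower and 1 higher. Dlx1 was also among the genes raised in 2 libraries with background sequence, while the pair numbered 1, which lacks it, had a median log2 ratio of -0.82 over the list. Zmiz1, named like Dll3 after its values were seen, also fell. The other 6 genes that fell were Xkrx, F830016B08Rik, Skint4, Psg28, Cyp2j5 and Slc6a18, likewise named after their values were seen. F830016B08Rik did not pass with a robust fit, and Xkrx did not with the block in DESeq2's Wald test. Of these 6, 4 hold LINE-1 sequence, and all 6 were near 0 in both replicate 1 libraries and high in Nanog+E-cadherin- replicates 2 and 3. In Nanog+E-cadherin+ replicates 2 and 3 their values lay between these, for example at 46.5 and 9.56 CPM for Xkrx.

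Several genes of the naive pluripotency list were higher in Nanog+E-cadherin+ cells, though a naive state was not tested. Tdgf1, a Nodal co-receptor, stood at 41.1 ± 40.2 CPM against 8.78 ± 8.59 CPM (SD, n = 3 each) and rose in the blocked fit (log2 fold change 2.23 ± 0.35 (SE), adjusted p = 0.0490 in edgeR's test), but did not pass with scaling by library totals or with a robust fit. The chromatin-associated Utf1 (13.95 against 0.827 CPM) and the threonine dehydrogenase Tdh (35.2 against 12.2 CPM) were higher in all 3 pairs. Of 23 genes tested, 18 were fitted higher and the median log2 fold change was 0.62 with group only. It was 0.14 without Nanog+E-cadherin+ replicate 1, 0.44 without Nanog+E-cadherin- replicate 2, and between 0.56 and 0.87 without any other library. Adjusted over all genes, 0 passed with group only and 1 with the block. Adjusted over the list alone, 0 passed with group only (2 without Nanog+E-cadherin- replicate 1) and 9 rose with the block, namely Tdgf1, Utf1, Tdh, Nr0b1, Fgf4, Sall4, Mybl2, Fbxo15 and Eras. Nanog, Dppa5a and Lin28a did not pass in any of these counts, and Esrrb and Zfp42 were below the filter, at 6.45 CPM or less in every library. The list passed camera (adjusted p = 2.51e-05), with an adjusted p = 0.147 with an estimated correlation and 0.358 with fry. Of 13 primed pluripotency genes none passed over all genes. With the block Otx2 and Sox4 fell when adjusted over the list alone, 0 passed with group only, and camera gave an adjusted p of 0.411. Without both libraries numbered 1 that blocked count was 0, and without those numbered 3 it was 3 higher and 2 lower.

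Several epithelial genes besides Cdh1 were higher in Nanog+E-cadherin+ cells, though few passed edgeR's test. Krt8, a simple-epithelium keratin, stood at 61.8 ± 41.8 CPM against 21.7 ± 8.33 CPM (SD, n = 3 each), while the adhesion molecule Epcam stood at 37.5 ± 7.08 CPM against 35.3 ± 4.64 CPM. Of 30 epithelial genes tested, 22 were fitted higher, with a median log2 fold change of 0.30 with group only and 0.48 with the block. Without Nanog+E-cadherin- replicate 2 it was 0.47, and without both libraries with background sequence 0.78. The libraries of both groups did not overlap for 10 higher genes and 1 lower gene, against 6.99% of all genes and 10% by chance for interchangeable libraries. With group only, 7 genes, all higher, had an unadjusted p under 0.05. Adjusted over all genes, 0 passed with group only and 1, Cdh1, with the block. Adjusted over the list alone, 1 passed with group only and 2, Cdh1 and Krt8, with the block. In blocked fits DESeq2 called 9 higher and 1 lower over the list alone, and limma-voom 7 higher and 1 lower. The list passed camera (adjusted p = 1.80e-09), with an adjusted p = 0.147 with an estimated correlation and 0.229 with fry. These list values and counts include Cdh1, whose protein set the sort gate, so they are not independent of the sorting. The list was not tested without Cdh1. Without both libraries numbered 3 the blocked count over the list alone was 8 higher and 1 lower. Of 8 keratinocyte and squamous genes tested, 5 were fitted higher, with a median log2 fold change of 1.17. Perp, a desmosome-associated target of p53, stood at 102 ± 15.9 CPM against 45.03 ± 14.9 CPM (SD, n = 3 each). None of the 8 passed over all genes in either fit. Adjusted over the list alone, 1, Perp, passed with group only (3 without Nanog+E-cadherin- replicate 1, and 0 without any other single library) and 3, Perp, Anxa8 and Krt13, with the block, and 5 without both libraries numbered 2, while the basal keratins Krt5 and Krt14 were below the filter. That list passed camera (adjusted p = 5.31e-07), with an adjusted p = 0.147 with an estimated correlation and 0.229 with fry.

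Mesenchymal and neural stem cell genes showed no change that passed over all genes. The intermediate filament gene Vim stood at 2194 ± 1096 CPM against 2273 ± 842 CPM, fibronectin (Fn1) at 921 ± 425 CPM against 781 ± 307 CPM, and the neural stem cell marker Nes at 201 ± 133 CPM against 199 ± 104 CPM (SD, n = 3 each). The transcriptional repressors of Cdh1, Zeb1 and Zeb2, had log2 fold changes of -0.32 ± 0.39 and -0.65 ± 0.33 (SE), and Snai1 and Snai2 stood below 2 CPM on average in both groups. Of 33 mesenchymal genes 20 were fitted lower, with a median of -0.08, and 0 passed over all genes or over the list alone in either fit, while with the block 2 fell over the list alone without both libraries numbered 1 and 3 without those numbered 2. Of 31 neural stem and radial glia genes 22 were fitted lower, with a median of -0.21. None passed with group only, and with the block 2, Hes5 and Msi1, fell when adjusted over the list alone. That count was 0 without both libraries numbered 1, 1 without those numbered 2 and 5 without those numbered 3, and it was 0 with the block and DESeq2 size factors. With the block it was 6 with GC and length offsets, 5 with limma-voom and 3 with DESeq2's Wald test. In the pairs numbered 1 to 3 the median log2 ratios were -0.26, -0.03 and -0.32 for mesenchymal and -0.07, -0.26 and -0.10 for neural stem genes. Leaving out 1 library with group only unbalances the replicate numbers, so the values that follow mix group with replicate number. Without Nanog+E-cadherin+ replicate 1 the group-only medians of both lists were above 0, at 0.25 and 0.10. They were also above 0 without Nanog+E-cadherin- replicate 2 (0.008 and 0.03) or 3 (0.19 and 0.19). Without both of these, with Nanog+E-cadherin- replicate 1 alone in its group, they were 1.09 and 1.01. Both medians were further under 0 without Nanog+E-cadherin+ replicate 2 (-0.33 and -0.31), Nanog+E-cadherin+ replicate 3 (-0.44 and -0.53) or Nanog+E-cadherin- replicate 1 (-0.48 and -0.49). Camera gave an adjusted p of 0.143 for the mesenchymal and 0.122 for the neural stem list with group only. With the block the values were 0.0231 and 0.00603, both toward lower, with an adjusted p = 0.512 and an adjusted p = 0.381 with an estimated correlation. The mesenchymal list passed toward higher, at 0.0359, without Nanog+E-cadherin+ replicate 1. It passed toward lower, at 0.00181, without Nanog+E-cadherin- replicate 1, at 3.70e-05 without Nanog+E-cadherin+ replicate 2 and at 0.00894 without Nanog+E-cadherin+ replicate 3. The neural stem list passed toward lower without Nanog+E-cadherin+ replicate 2 (0.0119), without Nanog+E-cadherin+ replicate 3 (5.38e-04) and without Nanog+E-cadherin- replicate 1 (0.00262).

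**Figure D2:**
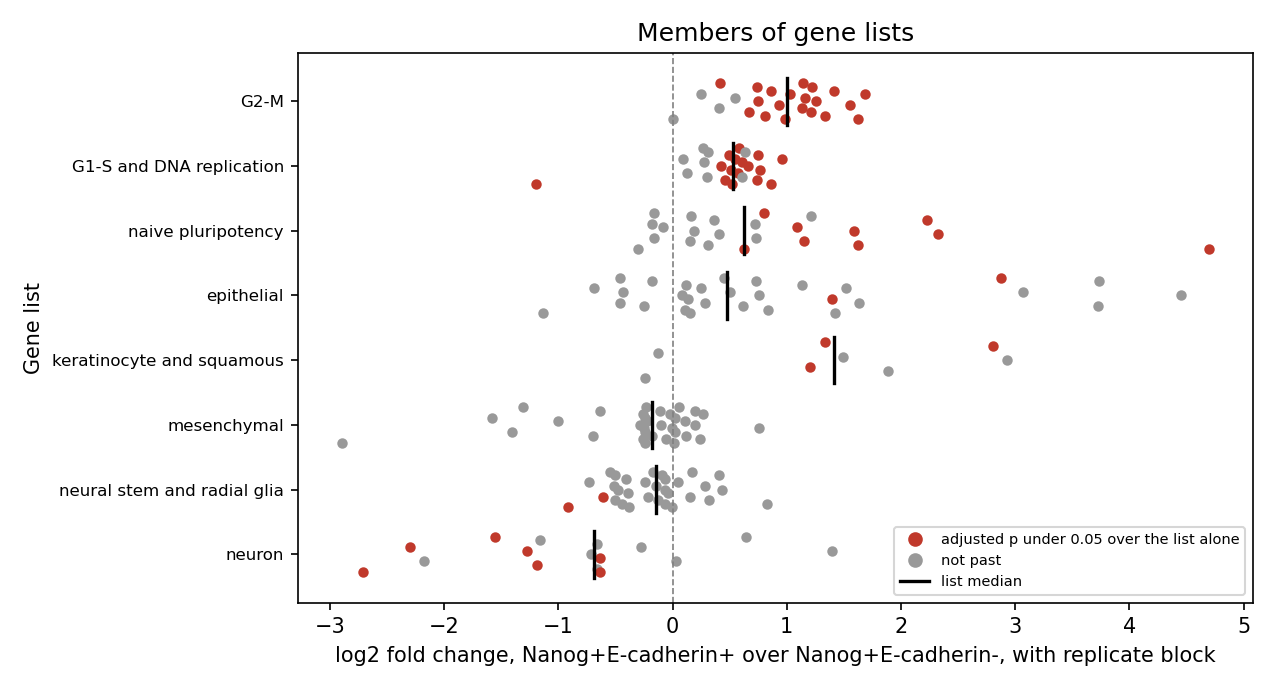
Each point is the log2 fold change of 1 gene (Nanog+E-cadherin+ over Nanog+E-cadherin-, fit with the replicate block, n = 3 per group), arranged by gene list. Red points passed an adjusted p of 0.05 over the list alone and black bars are list medians. Of the G2-M genes 20 of 24 are past the threshold on the right, and 7 of 16 neuron genes are past it on the left.

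The remaining lists did not pass camera with group only. Adjusted p-values were 0.843 for the reprogramming factors, 0.996 for oligodendrocyte, 0.843 for astrocyte, 0.843 for mesoderm and endoderm, 0.553 for trophoblast, 0.843 for germ cell and 0.264 for endothelial genes. They were 0.264 for p53, senescence and arrest genes, 0.264 for immediate early and stress genes, 0.264 for interferon response, 0.917 for glycolysis, 0.264 for oxidative phosphorylation and 0.0524 for cytosolic ribosomal proteins. They were 0.762 for DNA methylation and Polycomb genes, 0.843 for Notch and Wnt targets, 0.843 for BMP and TGF-beta targets, 0.672 for extracellular matrix and integrins and 0.122 for replication-dependent histones. With the block, immediate early genes (0.0434), oxidative phosphorylation (0.0353) and ribosomal proteins (5.05e-05) passed toward higher. Each of these had an adjusted p = 0.512 with an estimated correlation. Several calls turned on 1 library with group only. Leaving out 1 library unbalances the replicate numbers between groups, so these calls mix group with replicate number. Without Nanog+E-cadherin+ replicate 1, astrocyte (0.00561), endothelial (0.0396), p53 (0.0479) and extracellular matrix genes (4.99e-07) passed toward higher, and glycolysis (0.0479), oxidative phosphorylation (0.00717) and ribosomal proteins (0.0118) toward lower. Without Nanog+E-cadherin- replicate 1, immediate early genes (0.00680), glycolysis (0.00287), oxidative phosphorylation (8.28e-05) and ribosomal proteins (3.24e-08) passed toward higher. Without Nanog+E-cadherin+ replicate 2, immediate early genes (0.0173), oxidative phosphorylation (4.95e-04) and ribosomal proteins (9.22e-07) passed toward higher. Without Nanog+E-cadherin+ replicate 3, oxidative phosphorylation (0.00922) and ribosomal proteins (2.75e-04) passed toward higher and interferon response (0.0201) toward lower. Without Nanog+E-cadherin- replicate 3, endothelial (0.0172) and extracellular matrix genes (3.48e-04) passed toward higher. Camera's direction was up for germ cell (median log2 fold change -0.34, mean 0.002) and glycolysis genes (median -0.09, mean -0.02). For BMP and TGF-beta targets (0.20, -0.003) and extracellular matrix genes (0.006, -0.04) the median and the mean differed in sign. Each of these 4 medians changed sign without at least 1 library. Microglia and leukocyte genes were not tested, since only 2 of 16 passed the filter.

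Each Nanog+E-cadherin- library was closest to the Nanog+E-cadherin+ library of its number, and 2 of them held the most background sequence. Spearman's correlation across genes, which are not independent replicates, was 0.986, 0.964 and 0.940 within numbers 1 to 3. Nanog+E-cadherin+ replicates 2 and 3 were closer to each other (0.977) than to the Nanog+E-cadherin- libraries of their numbers, and replicate 3 was also closer to Nanog+E-cadherin- replicate 2 (0.946). The Y-linked genes Kdm5d, Ddx3y, Eif2s3y and Uty stood at 0.486 CPM of library totals or less in both libraries numbered 2, and at 3.53 CPM or more in the other 4. In Nanog+E-cadherin- replicates 2 and 3, 71 genes were above 5 CPM and above 3 times the highest of the other 4 libraries. Of the 69 with a transcript sequence 33 hold LINE-1 sequence, against 111 of 13436 genes tested. The same rule gave 29, 8 and 33 genes for the pairs numbered 1, 2 and 3, and at most 1 for any other 2 libraries. Of those genes 0 hold LINE-1 sequence. Together 187 genes holding LINE-1 sequence summed to 14480 and 8958 CPM of library totals in Nanog+E-cadherin- replicates 2 and 3. In the other 4 libraries they summed to between 2176 and 3188 CPM. Olfactory, vomeronasal and taste receptor genes without LINE-1 sequence summed to 43.6 and 12.5 CPM in Nanog+E-cadherin+ replicates 2 and 3. In the replicate 1 libraries of the Nanog+E-cadherin+ and Nanog+E-cadherin- groups they summed to 3.58 and 3.00 CPM. The background was thus graded, and leaving out both high libraries does not remove all of it. Lars2 stood at 6823 CPM in Nanog+E-cadherin- replicate 3 and between 414 and 648 CPM elsewhere.

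**Figure D3:**
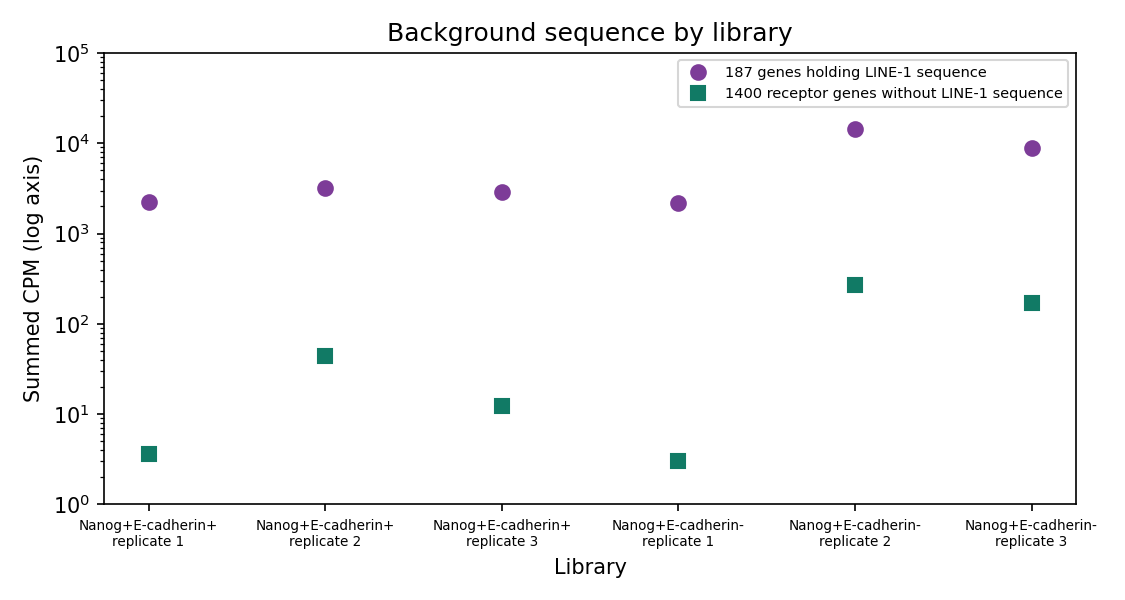
Each point is the summed CPM (log axis) in 1 library of genes whose transcripts hold LINE-1 sequence (purple circles) or of olfactory, vomeronasal and taste receptor genes without it (green squares). Both sums are highest in Nanog+E-cadherin- replicates 2 and 3, where the receptor genes sum to 270 and 169 CPM against at most 43.6 CPM in the other 4 libraries.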

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

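Settings that dropped LINE-1 genes, dropped both background libraries, corrected GC content and length, or altered the fit with the replicate block were chosen after seeing the data. With group only, 0 genes passed except for 1 (higher) with no filter on low counts and 21 (18 higher, 3 lower) with DESeq2's Wald test. With the replicate block edgeR called 41 (29 higher, 12 lower). Without any 1 library edgeR's group-only counts of all, higher and lower genes stayed at 0, with 164 to 1262 genes at an unadjusted p under 0.05. The Cdh1 log2 fold change passed at 2.90 with no filter, 2.90 with DESeq2 and 2.87 with the replicate block, and ranged from 2.81 to 3.02 without any 1 library. That of Nanog ranged from -0.05 to 0.34 without any 1 library and was -0.22 without both background libraries, where it did not pass. With the block, the count of 41 became 97 (67 higher, 30 lower) with GC and length offsets, 304 (185, 119) with DESeq2 and 264 (132, 132) with limma-voom. In simulated data DESeq2 with the block made 23 wrong calls with pairs and 87 without, and edgeR with 2 pairs made 25, against 4 with 3 pairs. Without both libraries of 1 number it ranged from 140 to 449, the higher genes from 84 to 247 and the lower from 45 to 202, with at least 40 of the 41 kept (Cyp2j5 was lost without number 2). The prior degrees of freedom then rose from 6.70 to between 14.0 and infinite, so a spread near the trend was assumed for each gene. With an estimated correlation the naive pluripotency list gave 0.147, epithelial 0.147, neuron 0.311 and G2-M 0.147, and with fry 0.358, 0.229, 0.560 and 0.229. With the replicate block the mesenchymal list gave 0.0231 and the neural stem list 0.00603, both lower; the block ended no list's call. Without any 1 library the range was 3.70e-05 to 0.861 for mesenchymal (lowest toward lower; toward higher 0.0359 without Nanog+E-cadherin+ replicate 1), 5.38e-04 to 0.932 for neural stem, and 3.83e-11 to 0.0727 for neuron. Glycolysis (0.00287 to 0.479), oxidative phosphorylation (8.28e-05 to 0.836) and ribosomal proteins (3.24e-08 to 0.993) passed toward lower without Nanog+E-cadherin+ replicate 1 (0.0479, 0.00717 and 0.0118) and toward higher at their lowest values. Leaving out 1 library unbalances the replicate numbers between groups, so these ranges mix group with replicate number. Ribosomal proteins also passed, at 0.00461 to 0.0447, with upper quartile factors, library totals, either other filter, limma-voom and log2 TPM, and endothelial genes with no filter (0.00596) and with at least 5 CPM (0.0222). Without both background libraries, a lone Nanog+E-cadherin- library is assumed to vary like the others and the replicate numbers are unbalanced. The direction then turned for the mesenchymal (5.09e-05), neural stem (2.74e-04), G1-S (0.401), immediate early (0.00508), interferon (2.74e-04), glycolysis (1.72e-07), oxidative phosphorylation (5.48e-07) and ribosomal (2.01e-08) lists. It also turned for oligodendrocyte (0.146), trophoblast (0.560), mesoderm and endoderm (0.553) and Notch and Wnt genes (0.318), which did not pass in either case. The cause was not tested. Of the named genes' other values, 41 newly passed, all with the replicate block or DESeq2, 44 changed sign by at least 1 SE without passing, 73 changed sign by less than 1 SE, and 2156 kept their direction and side of the threshold.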

Other observations

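The tests of explanations below were chosen after the results were seen. Genes outside the main lists also moved with the replicate block when adjusted over their list alone, and none of them passed over all genes or, with group only and all 6 libraries, over its list. The germline and early embryo gene Tex19.1 (14.01 ± 18.5 against 1.86 ± 3.07 CPM, SD, n = 3 each) and the germline gene Piwil2 (23.9 against 14.9 CPM) were higher in all 3 pairs. Among endothelial genes the receptors Eng (26.2 against 13.8 CPM) and Tek (29.15 against 16.8 CPM) were higher, and in glycolysis Eno1, the enolase, was (log2 fold change 1.04 ± 0.18, SE). The growth-arrest gene Gadd45g (94.9 against 209.9 CPM), the histone demethylase Kdm6b (129 against 194 CPM) and the imprinted Peg10 (198 against 277 CPM) were lower in all 3 pairs. The germ cell count of 2, and those of 1 for Kdm6b and Peg10, were 0 without both libraries numbered 1 (for Kdm6b also without those numbered 2), and the endothelial count of 2 was 0 without both libraries of any number.

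In Nanog+E-cadherin- replicates 2 and 3, 71 genes were raised, of which 33 of the 69 with a sequence hold LINE-1 sequence. LINE-1 reads alone are argued against as far as the word search reaches, since 33 of those genes held no LINE-1 word and receptor genes without LINE-1 sequence, silent in most cells, were raised too. A gene without such a word may still hold LINE-1 sequence that the search missed, as its words were widened from a starting set. Over these 1400 receptor genes the lower of both libraries summed to 3.89 times the highest of the other 4. Their reads were clumped, with 123 and 54 receptor genes at 10 or more reads but only 9 in common, against at most 3 such genes in the other libraries. A candidate explanation is amplified fragments of DNA or other non-messenger material in these 2 libraries, while a biological difference between the populations stays open and untested.

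Many G2-M genes were higher in Nanog+E-cadherin+ cells, with 17 of 24 past the threshold over their list with group only and all 6 libraries. That count was 0 without Nanog+E-cadherin+ replicate 1 or Nanog+E-cadherin- replicate 2, and 5 without Nanog+E-cadherin- replicate 3. It was 10 without Nanog+E-cadherin+ replicate 2, 16 without Nanog+E-cadherin+ replicate 3 and 18 without Nanog+E-cadherin- replicate 1. With the block 20 passed over the list, and 19, 20 and 23 did without both libraries numbered 1, 2 and 3. Scaling, which shifts all genes alike, is argued against, as the G2-M lower quartile of 0.72 in the blocked fit lay above the upper quartile of all genes, 0.26. The test of the background could not decide, since it asked for more than 1 Nanog+E-cadherin- library without background and only 1 lacks it. In the pair numbered 1, without it, the median was 1.06 with 24 of 24 genes higher. In that pair the rise was thus present without the background, while its part in the other pairs stays undecided. Without both background libraries the median was 0.75 (quartiles 0.55 and 0.93), against 1.02 (0.73 and 1.23) with all 6. That setting leaves Nanog+E-cadherin- replicate 1 alone in its group, so it mixes group with replicate number. Dilution of Nanog+E-cadherin- cells by non-cycling cells could not be decided: the G1-S median was 0.53 in the blocked fit, under that G2-M lower quartile. The comparison assumes that non-cycling cells would lower both lists alike, which was not tested, so it cannot decide on dilution. In the pair numbered 1 the G1-S upper quartile of 0.43 lay under the G2-M lower quartile of 0.86. In the pair numbered 2 these values were 0.82 and 0.80 (medians 0.66 and 1.13), and in the pair numbered 3 they were 0.91 and 0.37 (medians 0.67 and 0.70). A different share of cells in mitosis, or a gate that takes up larger cells, may also account for it and was not tested.

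Several neuron genes were lower in Nanog+E-cadherin+ cells with the block, where 7 of 16 passed over their list and 1 over all genes, while with group only and all 6 libraries 0 did (2 over their list without Nanog+E-cadherin- replicate 1). The 7 became 2 without both libraries numbered 1, and 4 lower and 1 higher without those numbered 2. The list gave an adjusted p of 0.311 with an estimated correlation and 0.560 with fry. The test of the background could not decide, as it asked for more than 1 Nanog+E-cadherin- library without background and only 1 lacks it. The pair numbered 1, without it, had a median log2 ratio of -0.82 with 14 of 16 genes lower. In that pair the fall was thus present without the background, while its part in the other pairs stays undecided. Without both background libraries the median was -1.13 with 20 of 20 lower. That setting has Nanog+E-cadherin- replicate 1 alone in its group, so it mixes group with replicate number. Tubb3, for example, stood at 342 CPM in Nanog+E-cadherin+ replicate 1, against 78.5 and 31.1 CPM in replicates 2 and 3 of that group. GC content and length are argued against by a median of -0.67 with offsets for both (-0.69 without), and 7 genes fell over the list alone in either case. Neurons among Nanog+E-cadherin- cells, which the Nanog gate should exclude, may account for part of it: of the 9 list genes of at least 10 CPM on average, 5 were lower by more than 2 SE in the blocked fit, but Stmn2, at 201 CPM, was not (0.03 ± 0.14, SE), nor were Gap43 (0.65 ± 0.54) and 2 others. A lower expression of these genes in the sorted cells themselves stays open and was not tested.

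The 6 samples split 3 against 3 in 10 ways, too few for a share under 0.05. Each of the 9 other splits still sets 2 libraries of 1 group against 2 of the other. A group difference can thus carry over into them, so they are not free of it. With group only all 10 splits called 0 genes in edgeR's test, the real one included (359 at an unadjusted p under 0.05; 21 with DESeq2 and 0 with limma-voom; highest other 0). Of the 4 splits that part all 3 pairs, the real one called 41 genes with the block and the highest other 0, so 1 of 4 reached that count. For gene lists past camera the real split gave 6 and the highest other 14, and 5 of 10 splits gave at least 6. The split with 14 sets replicate 1 of both groups with Nanog+E-cadherin+ replicate 3 against the rest. It keeps the libraries numbered 1 together and those numbered 2 together, but parts those numbered 3. It also sets receptor gene sums of 270, 169 and 43.6 CPM against 12.5, 3.58 and 3.00 CPM. Whether replicate number or background accounts for it was not tested. Of the 6 lists, G2-M passed in 6 of the 9 other splits (smallest adjusted p = 6.05e-14, real 5.49e-37), neuron in 3 (1.62e-06, real 1.04e-06) and G1-S in 3, with a smaller value in 1 (6.74e-09, real 2.29e-07). Naive pluripotency (smallest 4.09e-04), epithelial (2.30e-04) and keratinocyte genes (2.30e-04) passed in 2 each.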
